A study of Mus musculus with 40 samples.

How the data were processed

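Chromatin immunoprecipitation followed by sequencing was carried out on primary mouse bone marrow-derived macrophages from wild-type Csf1r-Cre animals and from Smarca5 knockout animals (floxed Smarca5 with Csf1r-Cre). The labels describe 40 libraries in 20 groups of 2. CTCF, PU.1 and C/EBPb have 4 libraries each, all from untreated cells. SMARCA5, profiled after micrococcal nuclease digestion, has 8 libraries from untreated cells and from cells given lipopolysaccharide (LPS) for 2 h. H3K27ac has 20 libraries, and its data were not analysed here.

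The material used was 4 consensus peak lists, 1 per immunoprecipitated protein for the whole series: narrow peaks with a summit for CTCF, PU.1 and C/EBPb, and broad peaks for SMARCA5. Per the submitters' processing notes, the tools were STAR 2.7.9a, Picard 2.27.4, MACS2 2.2.7.1 and deepTools 3.5.1, and the genome build was mm39. The role and order of these tools, the treatment of replicates, and the rule that made a consensus peak are not given in the sources used here. Each peak carries a deposited score, which lay within about 1 of 10 times the -log10 q for all peaks but 1. Each peak also has a deposited fold enrichment, read as the ratio over local background that MACS2 writes, and a deposited -log10 q. These are the authors' per-peak values, and their averaging over several calls is inferred here only from the decimals of the deposited scores. They were used only to describe, rank or filter peaks within a list. A total of 0 value columns and 0 peak names gave a library, a genotype or a stimulus. The lists for CTCF, PU.1 and C/EBPb may therefore hold peaks called in either genotype, and the SMARCA5 list was made in a series that includes Smarca5-deleted cells. Read depth per library is unknown.

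Peaks were compared by position with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. A peak was counted as overlapping when it shared at least 1 bp with a peak of the other list. Shares have 95% intervals from a bootstrap of 560 blocks of 5 Mb with 1000 draws, and differences between shares have the interval of the difference over the same draws. A difference was called when its interval left out 0. The chance level came from 1000 circular shifts of the second list within each of the 38 sequences, between the first start and the last end over the 4 lists, which together spanned 2654 Mb. The permutation p is one-sided, and 0.000999 is the smallest it can be. Peaks are not biological replicates, so intervals and p describe the placement of these lists along the genome and not the spread between animals or cultures. The shifts take no account of open chromatin, where all 4 proteins can bind.

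The overlap step was tested on simulated peaks. With 30.0% of peaks planted inside SMARCA5 peaks it recovered 30.2% for 25307 simulated CTCF peaks, 30.0% for 67796 PU.1 peaks and 29.9% for 30960 C/EBPb peaks. With 0 planted, the overlap was 0.945, 0.987 and 0.989 times the shifted level. With 70% of simulated scores averaged over 4 values and the rest over 2, the estimate of the former was 70.2% for CTCF, 69.5% for PU.1 and 70.5% for C/EBPb.

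The main tests, the alternatives and the rule for named regions were written before the data were examined, except where the closing part says otherwise. That plan did not hold the shares by distance from summits, the inner 50% of SMARCA5 peaks, or the distances between PU.1 and C/EBPb summits. It also did not hold the split by other factors at the same peak. Nor did it hold the groups of SMARCA5 peaks by width, fold enrichment or factors held, or the densities per chromosome. The alternatives tried were an overlap of 50% of the shorter peak, the summit inside the SMARCA5 peak, the upper 50% of the SMARCA5 list or of each factor's list by fold enrichment, all peaks resized to 200 bp, SMARCA5 peaks over 5 kb left out, autosomes only, the top 10000 peaks of each factor's list by fold enrichment, and ranking by -log10 q. Named regions are the 5 peaks of each list with the highest fold enrichment. Regions named for another reason were chosen after their values were seen, and this is said beside them.

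The gene table at hand is on GRCm38.p6 and the lists are on mm39, and no genome sequence was used. Coordinates were not converted. Genomic annotation, nearest genes, promoter and locus occupancy of the 20 gene lists fixed beforehand, motif content, and the alternatives that need gene starts were therefore not run. Comparisons of genotypes and of stimuli were not run either, since no value belonged to a library.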

Results

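The series profiled 4 chromatin-bound proteins and 1 histone mark in mouse bone marrow-derived macrophages, with and without Smarca5. SMARCA5 is the ATPase of ISWI chromatin remodelling complexes. PU.1 and C/EBPb are transcription factors that establish macrophage identity, and CTCF is a zinc-finger protein that marks insulators and chromatin loop anchors. The title of the series names lineage determination and inducible gene expression as the processes under study. CTCF, PU.1 and C/EBPb were profiled in untreated cells, with 2 wild-type and 2 Smarca5-deleted libraries each. SMARCA5 was profiled in 8 libraries, from both genotypes, untreated or after 2 h of LPS at 10 ng/ml. H3K27ac libraries covered both genotypes untreated and after 1 or 2 h of LPS at 10 ng/ml or interferon beta at 100 U/ml, and were not analysed here. Each of the 4 proteins was represented by 1 consensus peak list on mm39, so the comparisons below are between binding maps and not between genotypes or stimuli.

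PU.1 had the most peaks, 67796, against 30960 for C/EBPb and 25307 for CTCF. The 3 DNA-binding factors had narrow peaks, with median widths of 441 bp for PU.1, 436 bp for C/EBPb and 401 bp for CTCF. SMARCA5 had 37071 peaks with a median width of 2553 bp, and these covered 4.22% of the sequence spanned by the lists, against 1.22% for PU.1, 0.541% for C/EBPb and 0.391% for CTCF. The authors' fold enrichment had a median of 11.6 for CTCF, 11.3 for PU.1 and 11.7 for C/EBPb. SMARCA5 peaks had a median fold enrichment of 2.08 and a highest value of 3.54. These are broad-peak values and may not be comparable with those of narrow peaks.

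The SMARCA5 peak with the highest fold enrichment lay on chromosome 2 from 142452533 to 142453411 and overlapped peaks of CTCF and PU.1. Next came a peak on chromosome 7 from 103410429 to 103413370, at 3.52, which overlapped PU.1. All 5 leading SMARCA5 peaks overlapped a PU.1 peak, and 1 of them, on chromosome 9 from 114107790 to 114108848, also overlapped C/EBPb. The leading PU.1 peak, on chromosome 14 from 103724302 to 103724909 with a fold enrichment of 35.5, overlapped both SMARCA5 and C/EBPb. Of the 5 leading PU.1 peaks, 3 overlapped SMARCA5 and 3 overlapped C/EBPb. All 5 leading C/EBPb peaks overlapped PU.1 and 2 overlapped SMARCA5, among them the peak on chromosome 13 from 51864691 to 51865260 at 35.1. Among the 5 leading CTCF peaks, those on chromosome 12 from 3159872 to 3160117 and on chromosome 6 from 103626012 to 103626254 overlapped no other list, and had -log10 q values of 4643.51 and 4713.78 over widths of 246 and 243 bp. The other 3 overlapped both SMARCA5 and PU.1, as on chromosome 11 from 102993424 to 102993910, where the CTCF fold enrichment was 31.2. A filter on contigs and on -log10 q above 2000 would remove those 2 CTCF peaks, the first 3 C/EBPb peaks, of which 1 lay on an unplaced contig, and the PU.1 peak of rank 5 on the same contig.

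The overlap of each factor with SMARCA5 asked where peaks of the SMARCA5 list lay relative to those of DNA-binding proteins. No value was tied to a genotype, so whether SMARCA5 peaks depend on the protein could not be checked. SMARCA5 peaks overlapped 59.5% of C/EBPb peaks (95% interval 58.8 to 60.3), 49.5% of PU.1 peaks (48.9 to 50.0) and 39.9% of CTCF peaks (39.0 to 40.7). Shifted SMARCA5 peaks overlapped 5.31%, 5.33% and 5.26% of them. The observed overlap was 11.2, 9.28 and 7.57 times the shifted level, and for each factor the permutation p was 0.000999, the smallest the shifts can give. Of SMARCA5 peaks, 72.6% held a PU.1 peak (72.0 to 73.2). A C/EBPb peak was held by 44.4% (43.8 to 44.9) and a CTCF peak by 25.5% (24.7 to 26.2). The shifted levels were 8.71%, 4.17% and 3.44%, so the observed shares were 8.33, 10.6 and 7.40 times these for PU.1, C/EBPb and CTCF.

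Coverage by SMARCA5 peaks was highest at the summits of the factors. The share of positions inside a SMARCA5 peak was 58.4% at C/EBPb summits, 40.6% at 1000 bp from them and 15.5% at 5000 bp. For PU.1 the shares were 48.4%, 32.5% and 13.0%, and for CTCF 38.6%, 21.7% and 9.60%. At 50000 bp they were 11.4% for C/EBPb, 10.6% for PU.1 and 9.25% for CTCF. For summits, shifted SMARCA5 peaks gave 4.61%, 4.61% and 4.64% in the same order. The multiples over the shifted level thus include a regional excess that reaches beyond the peaks. Among summits inside a SMARCA5 peak, 64.5% of C/EBPb summits (63.8 to 65.1), 63.9% of PU.1 summits (63.4 to 64.4) and 56.2% of CTCF summits (55.3 to 57.2) lay in its inner 50%, where even placement would put 50%.

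**Figure D1:**
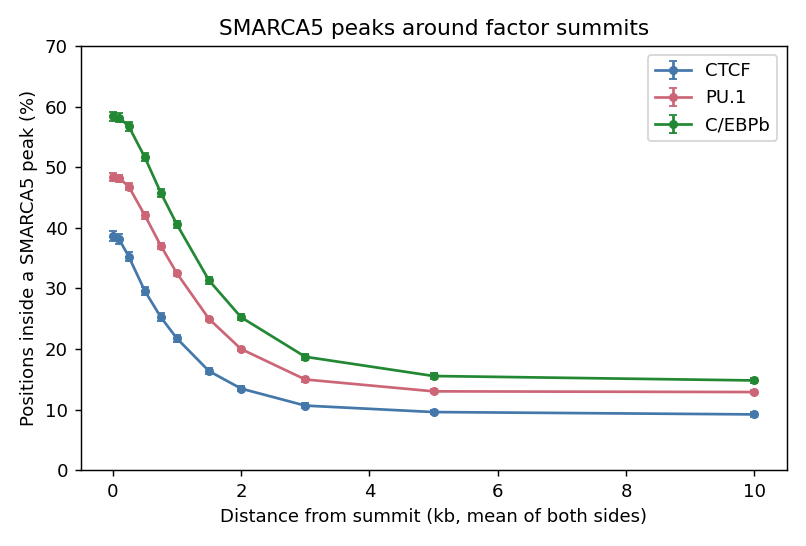
Share of positions inside a SMARCA5 peak (%, vertical axis) against distance from the summits of CTCF, PU.1 and C/EBPb peaks (kb, horizontal axis, mean of both sides), with 95% block bootstrap intervals as bars. The share is highest at the summit for each factor, 58.4% for C/EBPb, 48.4% for PU.1 and 38.6% for CTCF, and falls within a few kb.

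Over all peaks the 3 factors differed in how often they overlapped SMARCA5. C/EBPb exceeded PU.1 by 10.1 percentage points (9.55 to 10.6), PU.1 exceeded CTCF by 9.60 (8.77 to 10.5), and C/EBPb exceeded CTCF by 19.7 (18.8 to 20.6). The order of PU.1 and C/EBPb depended on how strong peaks were taken. In the upper 50% of each list by fold enrichment, C/EBPb stayed above PU.1, at 56.3% against 52.0%, a difference of 4.28 points (3.47 to 5.10). The order turned when equal numbers of peaks were taken, which is a smaller part of the longer PU.1 list. In the top 10000 peaks of each list by fold enrichment, 63.6% of PU.1 peaks and 60.2% of C/EBPb peaks overlapped SMARCA5, and C/EBPb minus PU.1 was -3.39 points (-4.66 to -2.06). In the top 10000 by -log10 q, chosen after the data were seen, the shares were 81.0% and 67.7% and the difference was -13.3 points (-14.6 to -12.1). CTCF stayed lowest in both, at 49.5% and 54.7%. Lists of different lengths reach different depths of binding, and the number of reads behind each is unknown.

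PU.1 and C/EBPb shared many sites, and CTCF overlapped both above the shifted level. Of C/EBPb peaks, 58.8% overlapped a PU.1 peak (58.1 to 59.3), which was 22.4 times the shifted level of 2.63%. C/EBPb peaks were found at 26.8% of PU.1 peaks (26.5 to 27.2). Of C/EBPb summits, 25.3% lay within 50 bp of a PU.1 summit (24.8 to 25.8) and 39.2% within 100 bp (38.6 to 39.7). CTCF peaks overlapped PU.1 in 19.9% of cases (19.4 to 20.5), 8.05 times the shifted level, and C/EBPb in 8.90% (8.51 to 9.28), 7.94 times. The permutation p was 0.000999 for each of these pairs, the smallest the shifts can give. Merged into 92529 regions, the lists gave 28320 regions with PU.1 alone, 13401 with CTCF alone, 7487 with C/EBPb alone and 5475 with SMARCA5 alone. The most frequent combination was SMARCA5 with PU.1 and C/EBPb, in 11681 regions, and all 4 proteins met in 3106.

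SMARCA5 peaks were found more often at sites shared by factors than at sites of a single factor. PU.1 peaks that overlapped neither C/EBPb nor CTCF met SMARCA5 in 38.4% of cases (37.8 to 39.1). With C/EBPb the share was 73.3% (72.5 to 74.0), with CTCF 65.5% (63.9 to 67.1), and with both 84.0% (82.0 to 85.9). C/EBPb peaks without PU.1 or CTCF met SMARCA5 in 37.2% of cases (36.2 to 38.1), against 73.4% with PU.1 (72.6 to 74.1). CTCF peaks on their own did so in 30.8% (30.0 to 31.6), against 66.3% with PU.1 (64.6 to 67.8) and 83.1% with PU.1 and C/EBPb (80.9 to 85.2). The gain over single-factor sites was 34.8 points for PU.1 with C/EBPb (34.0 to 35.6), 36.2 for C/EBPb with PU.1 (35.2 to 37.3) and 35.5 for CTCF with PU.1 (33.8 to 37.1). These gains are not adjusted for peak strength. The median -log10 q was 72.1 for CTCF with PU.1 against 48.3 for CTCF with neither. It was 91.3 for PU.1 with C/EBPb against 41.6, and 51.0 for C/EBPb with PU.1 against 47.7. At sites of a single factor, C/EBPb minus PU.1 was -1.27 points (-2.18 to -0.317), and PU.1 exceeded CTCF by 7.65 points (6.66 to 8.60). Single-factor peaks made up 67.9% of the PU.1 list and 38.5% of the C/EBPb list. With CTCF but not PU.1, 60.2% of C/EBPb peaks met SMARCA5, and with both 83.6%. Peaks with both PU.1 and C/EBPb are largely the same places counted from each list, so their shares are bound to be close. In the other classes the share was lower for C/EBPb, at 37.2% against 38.4% for single-factor peaks and 60.2% against 65.5% with CTCF. The 10.1-point excess of C/EBPb over all peaks went with the make-up of the lists.

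**Figure D2:**
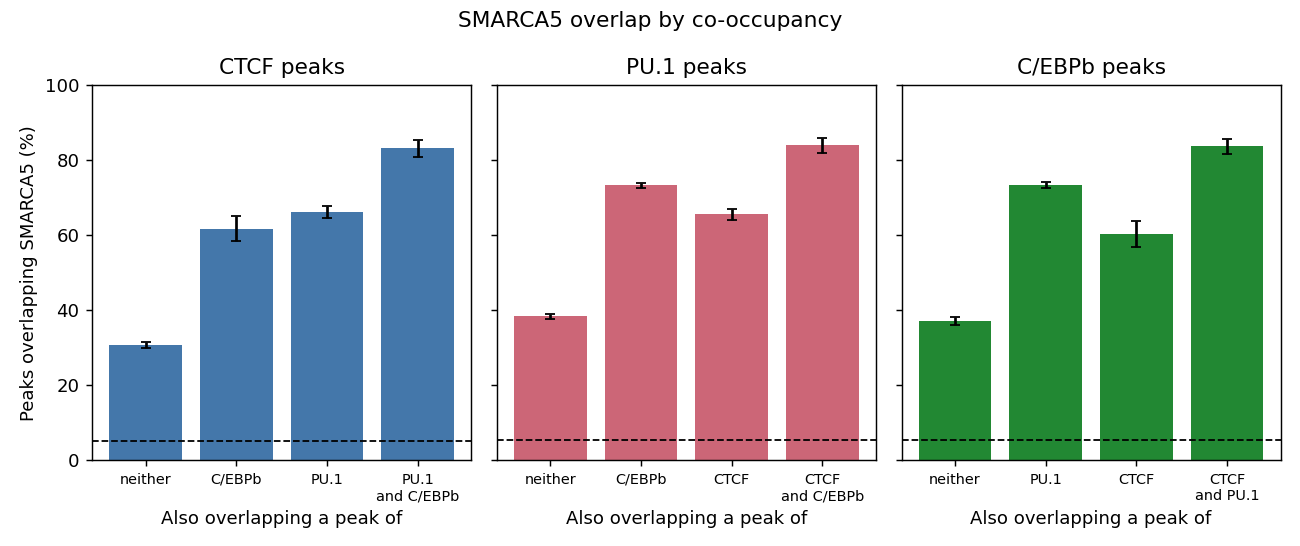
Share of CTCF, PU.1 and C/EBPb peaks that overlap a SMARCA5 peak (%, vertical axis), split by which of the other 2 factors they also overlap (horizontal axis); bars have 95% block bootstrap intervals and dashed lines mark the mean of the circular shifts for all peaks of that factor. PU.1 peaks rise from 38.4% with neither factor to 84.0% with both.

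Among the regions with all 4 proteins, 3 that ranked high in every list were chosen after their values were seen. On chromosome X from 158897653 to 158900162, the fold enrichment was 2.43 for SMARCA5, 16.4 for CTCF, 29.2 for PU.1 and 26.96 for C/EBPb. On chromosome 19 from 23735171 to 23739956 the values were 2.33, 25.4, 20.9 and 29.6 in the same order. On chromosome 4 from 55821895 to 55825542 they were 2.36, 21.3, 25.5 and 22.9. The SMARCA5 peak with the most factor summits, also chosen afterwards, spanned chromosome 16 from 23796474 to 23814496 and held 4 CTCF, 3 PU.1 and 4 C/EBPb summits.

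Stronger CTCF peaks overlapped SMARCA5 more often. Ranked by fold enrichment, the share was 38.6% in decile 1, 30.8% in decile 3 and 63.1% in decile 10 of the CTCF list, a difference of 24.5 points (21.6 to 27.1). PU.1 had 66.6% in decile 1, 39.4% in decile 4 and 66.0% in decile 10, and decile 10 minus decile 1 was -0.605 points (-2.19 to 1.01), which did not differ from 0. C/EBPb had 77.4% in decile 1, 48.9% in decile 6 and 70.5% in decile 10, a difference of -6.82 points (-9.11 to -4.45). Ranked by -log10 q, decile 10 exceeded decile 1 for all 3 factors. The differences were then 43.9 points for CTCF (41.4 to 46.4), 47.9 for PU.1 (46.2 to 49.4) and 11.9 for C/EBPb (9.48 to 14.0). The direction for C/EBPb thus depended on the ranking measure, and PU.1 differed from 0 only by -log10 q.

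**Figure D3:**
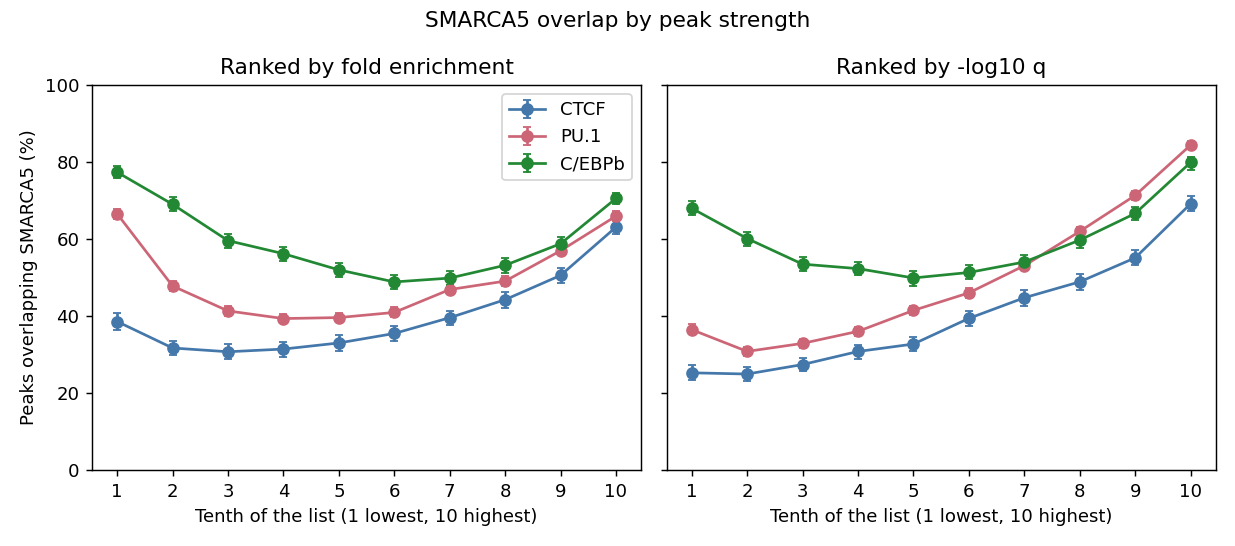
Share of peaks that overlap SMARCA5 (%, vertical axis) by decile of each factor's list (horizontal axis, 1 lowest and 10 highest), ranked by fold enrichment on the left and by -log10 q on the right, with 95% block bootstrap intervals. By fold enrichment C/EBPb falls from 77.4% to 48.9% in decile 6 and returns to 70.5%, and by -log10 q PU.1 reaches 84.4% in decile 10.

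Most SMARCA5 peaks held PU.1, alone or with C/EBPb. Of all SMARCA5 peaks, 31.5% held PU.1 and C/EBPb without CTCF (30.9 to 32.1), 24.8% PU.1 alone (24.3 to 25.3) and 8.08% CTCF alone (7.76 to 8.37). Peaks with none of the 3 factors made up 14.8% (14.2 to 15.3), or 5475 peaks. The factors were profiled only in untreated cells, and SMARCA5 also after LPS. These peaks therefore cannot be taken as free of the factors in both conditions. The median width of SMARCA5 peaks was 1666 bp with none of the factors, 1537 bp with CTCF alone, 2156 bp with C/EBPb alone and 2391 bp with PU.1 alone. It was 3205 bp with PU.1 and C/EBPb and 3817 bp with all 3 factors.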

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

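The score column was used in no comparison above, and its decimals carried a signal of their own; the standardised comparison below was planned before its result was seen, while the split of peaks by number of averaged values, the larger minimums and the test of genotype were chosen after the values had been seen. Scores had a decimal part of 0.25 or 0.75 for 24768 PU.1 peaks, 10328 C/EBPb peaks, 9426 CTCF peaks and 7154 SMARCA5 peaks, where a count of 0 would have followed from scores made of 1 call or of 2. All other scores were whole or had a decimal part of 0.5. If a score averaged over 4 whole numbers has such a decimal part 50% of the time, an estimated 73.1% of PU.1, 66.7% of C/EBPb, 74.5% of CTCF and 38.6% of SMARCA5 peaks were averaged over 4 values and the rest over 2. SMARCA5 had 8 libraries, but 0 of its scores had the other decimal parts that an average over 8 values would often give. Whether a value stands for 1 library or for more is not given. The averaging is inferred from the decimals alone, since no source used here states it, and the shares that follow rest on it.

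Under that estimate, peaks averaged over 4 values overlapped SMARCA5 more often than those averaged over 2, by an estimated 57.7% against 27.2% for PU.1, 68.6% against 41.5% for C/EBPb and 44.0% against 27.8% for CTCF. Deciles of -log10 q cannot decide whether stronger peaks were the whole cause. The -log10 q follows the score, so under that estimate it was averaged over the same 2 or 4 values. Peaks of the same decile may therefore differ in strength over all libraries. Within these deciles the difference was 20.8 points for PU.1 (18.1 to 23.9) and 29.9 for C/EBPb (27.4 to 32.7). For CTCF it was 5.85 points (1.73 to 9.84), down from 16.1, and 6.30 (2.72 to 9.69) with at least 200 estimated 2-value peaks per decile, which kept 93.7% of them, but 2.00 (-1.37 to 5.40) with at least 400, which kept 61.2%, so part of the CTCF difference may follow peak strength. Calls that entered 1 library at a time would often leave other decimal parts, and 0 scores of any list had one. Under the same estimate, this argues against such single entry. Which calls entered together is not given, and 0 columns or peak names tie a call to a genotype. Whether the 2-value peaks were called in 1 genotype therefore cannot be told apart from paired calls in 1 replicate of each. No biological explanation was tested.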

How the results depend on the processing

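Of the alternatives below, the removal of contigs, mitochondrial sequence and -log10 q above 2000, the top 10000 peaks by -log10 q, and the summit rule for peak strength were chosen after seeing the data. The overlap of each factor with SMARCA5 stayed above the shifted level in all 24 values, from 7.51 to 20.8 times, and the pairwise overlaps of factors did so in all 12, from 7.42 to 42.4 times. Of 30 differences between factors, 28 kept their direction with an interval that left out 0. Sizes fell where the setting lowered all shares. Without SMARCA5 peaks over 5 kb, with the upper 50% of the SMARCA5 list and at 200 bp, C/EBPb minus PU.1 was 6.61, 3.14 and 1.88 points. C/EBPb minus CTCF was then 11.4, 5.31 and 3.16. Differences from CTCF also fell in the upper 50% of each factor's list, where the CTCF share rose to 46.6%. There C/EBPb minus CTCF was 9.65 points and PU.1 minus CTCF 5.37. In the top 10000 peaks by fold enrichment, C/EBPb minus CTCF fell to 10.6 while PU.1 minus CTCF rose to 14.0. Under the 50% overlap, summit and autosome rules, C/EBPb minus PU.1 stayed at 9.99 to 10.2. C/EBPb minus PU.1 turned to -3.39 points in the top 10000 peaks by fold enrichment and to -13.3 by -log10 q, but was 4.28 in the upper 50% of each factor's list; the cause was not tested. Of 9 values for peak strength, 6 kept their direction and call. Ranked by -log10 q, decile 10 minus decile 1 went from -0.605 to 47.9 points for PU.1 and turned from -6.82 to 11.9 for C/EBPb, and with the summit inside the SMARCA5 peak the PU.1 value was 0.737; the cause was not tested. The intervals of -0.605 and 0.737 both held 0. Resizing all peaks to 200 bp lowered the shares to 9.48% for CTCF, 10.8% for PU.1 and 12.6% for C/EBPb, as its construction implies for SMARCA5 peaks several kb wide. Alternatives that need gene starts on mm39 were not run. No paired analysis was possible because the lists hold no values per library. Depth per library is unknown, so weak sites missing from a list cannot be taken as unbound.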

Other observations

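CTCF sat differently in the SMARCA5 landscape from the myeloid factors. From the narrowest to the widest of 5 equal groups of SMARCA5 peaks, with median widths of 907 and 5590.5 bp, the share that held PU.1 went from 48.6% to 89.8% and the share that held C/EBPb from 22.8% to 66.3%. For CTCF it was 27.3% and 27.1%, a difference of -0.226 points (-1.67 to 1.08). Wider peaks meet more sites by chance, and against the shifted level CTCF fell from 20.3 to 4.11 times, PU.1 from 13.1 to 5.70 times and C/EBPb from 13.5 to 8.46 times. By SMARCA5 fold enrichment, the highest of 5 groups held C/EBPb less often than the lowest, by -15.1 points (-16.8 to -13.6). It also held PU.1 less often, by -7.10 points (-8.72 to -5.47), and CTCF more often, by 2.98 points (1.49 to 4.59). The highest group was also narrower, with a median width of 2093 bp against 2859 bp. Against the shifted level the highest group was not below the lowest. From lowest to highest it was 11.1 and 11.2 times for C/EBPb, with 10.1 to 10.5 in the groups between. It was 7.85 and 9.84 times for PU.1 and 5.96 and 9.68 for CTCF.

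Chromosome X had fewer peaks per Mb than the autosome median in all 4 lists. It had 9.63 PU.1 peaks per Mb against an autosome median of 26.8, 4.09 against 12.2 for C/EBPb, 3.55 against 10.3 for CTCF and 4.67 against 14.4 for SMARCA5. A few regions had extreme values in several lists and were chosen after their values were seen. The highest -log10 q of the CTCF list, 24675.8, was on chromosome 2 from 98496627 to 98497669, a place that also held the highest PU.1 and C/EBPb values and no SMARCA5 peak. The highest SMARCA5 value, 363, was on chromosome 17 from 40153914 to 40159661, where the fold enrichment was only 1.65. No list of regions with unreliable signal was used to filter peaks here, so such extreme values need not reflect binding. The mitochondrial sequence held 3 C/EBPb and 2 SMARCA5 peaks, and unplaced or unlocalised contigs held 59 PU.1, 30 C/EBPb, 14 CTCF and 11 SMARCA5 peaks.

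For the patterns below, the tests by ranking measure and by width of low-ranked peaks were chosen after the decile shares had been seen, and the other tests were written before their results. The lowest fold decile of all 3 factors overlapped SMARCA5 more often than deciles 5 and 6, by 26.3 points for PU.1 (24.8 to 27.8), 26.9 for C/EBPb (24.9 to 28.8) and 4.34 for CTCF (1.78 to 6.89), and explanations were tested for PU.1 and C/EBPb. Wider peaks as the whole cause were argued against, since the lowest decile held fewer peaks wider than the median of deciles 5 and 6, by -14.0 points for PU.1 (-15.5 to -12.4) and -6.90 for C/EBPb (-9.30 to -4.67). So was a listed peak of another of the 3 factors at the same place. Among peaks that overlapped no such peak, the excess was 30.2 (28.4 to 32.0) and 30.6 (26.9 to 34.3). Proteins without a list here, and sites too weak to be listed, were not tested. Ranked by -log10 q, the PU.1 value was -7.27 (-8.63 to -5.71). The use of fold enrichment as the measure may thus account for the PU.1 excess over deciles 5 and 6. By -log10 q, PU.1 decile 1, at 36.5% (35.3 to 37.9), still lay above decile 2, at 30.8% (29.6 to 32.0). C/EBPb kept an excess over deciles 5 and 6 of 17.4 (15.4 to 19.6). Background raised by open chromatin, which would lower the fold at such sites, stays open and was not tested, and no biological explanation was tested.

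PU.1 peaks that overlapped C/EBPb, with or without CTCF, met SMARCA5 in 74.1% of cases against 38.4% for PU.1 on its own, a difference of 35.7 points (34.9 to 36.4). Within deciles of -log10 q it was 24.6 points (23.8 to 25.3), within deciles of width 25.2 (24.3 to 26.0), and with SMARCA5 peaks at or below their median width 11.4 (10.6 to 12.1), from shares of 24.9% and 13.5%. Wider peaks and wide SMARCA5 peaks are each argued against as the whole cause, while stronger or wider peaks may account for a part. Deciles of -log10 q cannot decide whether stronger peaks were the whole cause. As described above, the -log10 q may average different numbers of values, so peaks of the same decile may differ in strength over all libraries. Leaving out the wider SMARCA5 peaks lowers both shares by construction. The fall to 11.4 points therefore cannot show what part wide SMARCA5 peaks account for. Shared open chromatin was not tested, nor was a biological explanation.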
